A study of Drosophila melanogaster with 9 samples.

How the data were processed

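Transcript levels were measured with Affymetrix arrays in heads of Drosophila melanogaster of a strain that the labels call 5073. Heads were sampled at 6 zeitgeber times spaced 4 h apart, where zeitgeber time (ZT) counts hours from lights-on. The labels place 9 arrays in 6 groups: 3 arrays at ZT3, 2 at ZT15, and 1 each at ZT7, ZT11, ZT19 and ZT23. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin. The labels give no sex, age, light schedule or description of the strain, and arrays of a control strain were not used here. Whether the strain is wild type or a mutant, of the clock or otherwise, is thus unknown here, and levels and amplitudes of clock genes were not set against those of wild-type flies.

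Per the submitters' processing notes, the authors made their values with GCRMA, which corrects background with the probe sequence, normalizes arrays together and summarises each probe set on a log2 scale. Its version and settings are not given in the sources used here. The deposited table holds 1 value per probe set and array, from 5.31 to 8120023. Their base was worked out from the values: log2 of the deposited values reached 22.95, beyond the range of a 16-bit scanner, while their natural log ran from 1.67 to 15.91. The hybridization controls bioB, bioC, bioD and cre, added by the array protocol at 1.5, 5, 25 and 100 pM, rose with log2 concentration with a slope of 1.03 ± 0.0584 (SD over the 9 arrays, range 0.939 to 1.09) when the natural log of the deposited values was used. The slope was 1.49 (range 1.35 to 1.57) when log2 was used. The natural log of the deposited values was therefore taken as the authors' log2 GCRMA value, and all levels and differences are on that scale. If log2 of the deposited values were the true scale, every fold would be raised to the power 1.44, so that a 2-fold difference would read 2.72-fold. Directions do not depend on this choice.

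The table held 18952 probe sets, of which 183 were control probe sets and were left out. Gene names came from the platform annotation, updated through Entrez gene identifiers with a current RefSeq gene table. Of the 18769 other probe sets, 13647 named 1 gene, 402 named several and 4720 named none here; 13544 of the first kind matched by identifier. A total of 11982 genes were named. Probe sets naming several genes or none carry their own identifier and no gene name. Genes that no probe set named here, among them the opsin genes ninaE and Rh3 to Rh6, were not analysed here. A gene with several probe sets was represented in list tests by the one with the highest mean over the 9 arrays. Probe sets were tested if they reached 5 on the log2 scale on at least 2 arrays, which left 12105 probe sets and 9659 genes. No coordinates are given, because the build behind the annotation is not named.

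The following choices were made before the data were examined. ZT15 was compared with ZT3, the only times with replicates, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 group means over the 9 arrays, residual df of 3). A rhythm was tested over all 9 arrays with limma's moderated F for a cosine and a sine of 24 h (residual df of 6); amplitude is the size of the fitted cosine on the log2 scale, and peak time its maximum. All limma p-values were adjusted by Benjamini-Hochberg over the probe sets tested, two-sided, with a threshold of 0.05. Standard errors come from these fits. Lists were compared with all other genes by limma's camera with a preset correlation of 0.01, with an estimated correlation beside it. limma's fry, which tests a list without reference to other genes, was also run, and its p-values are given unadjusted. Rhythmic genes were counted in each list with a one-sided Fisher exact test. The camera and Fisher tests were adjusted over the 22 lists with at least 5 tested members.

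The 24 gene lists were core clock genes, clock modifiers, genes known to cycle in heads, clock neuropeptides, phototransduction, synapse, glia, fat body, muscle, hemocyte, gut, testis and accessory gland, ovary, sex-specific dosage compensation, antimicrobial peptides, heat shock, cytochrome P450s, glutathione S-transferases, UDP-glycosyltransferases, cytosolic and mitochondrial ribosomal proteins, proteasome, odorant-binding proteins, and lipid and carbohydrate metabolism. Genes were named by rule. All core clock genes were named in both comparisons. For ZT15 against ZT3, the 10 largest changes in each direction past the threshold, with both ZT15 arrays on the same side of all 3 ZT3 arrays, were to be named, or the 10 genes of smallest p if fewer than 6 passed. For the rhythm, the 20 genes of largest amplitude past the threshold were to be named, or the 10 of smallest p. In each list up to 4 members past the threshold were to be named, or up to 2 of smallest p. The rule was applied to the rhythm with the 2-array block described below as well. Where 5 or fewer members of a list passed over the list alone, all were named, and those outside the rule were chosen after their values were seen.

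A split of the arrays was found in the data: ZT3 replicate 1 and ZT15 replicate 2 stood apart from the other 7 arrays (the 2-array set). Fits with this set as a block, fits without it, and fits with the mean level of the testis and accessory gland list as a covariate were added after this split had been seen. Because the set holds 1 array of each replicated time, the difference between ZT15 and ZT3 is also given within it (ZT15 replicate 2 minus ZT3 replicate 1) and within the other arrays (ZT15 replicate 1 minus the mean of ZT3 replicates 2 and 3). Nothing in the labels says that replicates came from separate groups of flies, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision: 4 of the 6 times have a single array.

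Other settings tried were quantile normalization, centring each array on its median, no filter and a filter at 7, a pseudocount of 16, eBayes with trend and robust, array weights, averaging the probe sets of a gene, an adjusted p of 0.10, a minimum of 2-fold, leaving out each array, the replicate number as a block, ZT3 and ZT15 arrays alone, 1 mean per time, time as a factor and a 12 h cosine. The fits were tested on simulated data of 12105 probe sets, with normal noise around the real probe set means at the spreads estimated by each fit, in which 50 probe sets were changed at each of 4 sizes. Such noise does not carry the split between the real arrays, so its false calls do not stand for those in the real data. For ZT15 against ZT3, 0% of changes of 1 on the log2 scale and 42% of changes of 2 were recovered, with 4 false calls; with the block these were 46% and 86%, with 8. For the rhythm, 24% of curves with a peak-to-trough difference of 1 and 64% of those with 2 were recovered, with 8 false calls; with the block these were 62% and 86%, with 16. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.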

Results

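Fly head transcripts were measured around the 24 h day at ZT3, ZT7, ZT11, ZT15, ZT19 and ZT23 on 9 arrays of the 5073 strain, to follow which transcripts change with time of day. Median levels per array lay between 6.05 and 6.65 on the log2 scale, and 10534 to 11577 probe sets per array reached 5. Both were lowest in ZT3 replicate 1 (6.06 and 10584) and ZT15 replicate 2 (6.05 and 10534). The mean level of the added bioB control was 9.38 and 9.28 in these arrays. It was 9.04 and 8.21 in ZT3 replicates 2 and 3, and 7.43 to 8.06 in the rest.

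The arrays carried different amounts of transcripts listed as markers of other body parts. The testis and accessory gland list, 19 genes for sperm and seminal fluid proteins, had a median level of 3.67 in ZT3 replicate 1 and 3.32 in ZT15 replicate 2, and between 9.75 and 11.72 in the other 7 arrays. All 19 of its genes were lower in both of these arrays than in all 7 others, as were 17.3% of all tested probe sets. These arrays were set apart after the values were seen, so the count was largely fixed by that choice. The gut list, mostly digestive proteases, had medians of 5.37, 5.47 and 4.96 in the ZT3 arrays and 4.32 in ZT15 replicate 2, and between 8.77 and 10.47 in the other 5 arrays. The ovary list, egg shell and germline genes, stayed between 3.29 and 3.72 in all 9 arrays, with too few members above the filter for a list test. The phototransduction list, genes of the light response of the eye, stayed between 11.75 and 12.44. The fat body genes Yp1, Yp2 and Yp3, which encode yolk proteins made in females, lay between 15.2 and 15.9 in all arrays. The dosage compensation list was measured by msl-2 alone, at 8.10 to 8.71. The first principal component held 83.2% of the variance between arrays and set the 2-array set (loadings 0.57 and 0.59) against the ZT7, ZT11, ZT15 replicate 1, ZT19 and ZT23 arrays (-0.19 to -0.32), with ZT3 replicates 2 and 3 between them (0.05 each). These 2 arrays correlated at r = 0.988 across probe sets, and at 0.752 to 0.905 with the others, which correlated among themselves at 0.915 or more. Probe sets are not independent replicates.

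**Figure D1:**
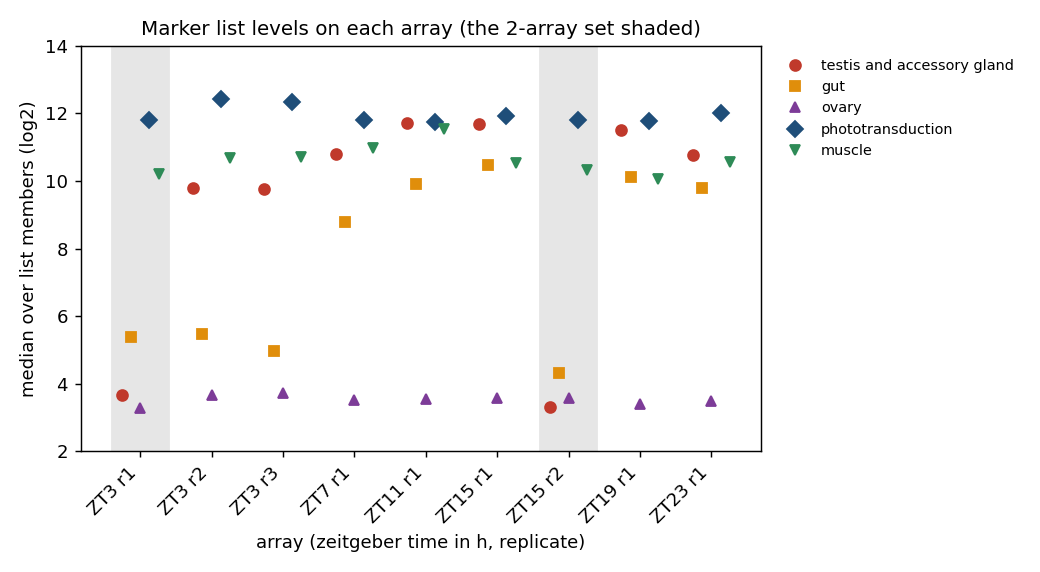
Median level (log2) of the members of 5 marker lists on each of the 9 arrays; each point is 1 list on 1 array, the horizontal axis gives zeitgeber time in h and replicate (r), and points are offset sideways for legibility. The testis and accessory gland list sits at 3.67 and 3.32 in the shaded arrays and between 9.75 and 11.72 in the other 7.

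Between ZT15 and ZT3 the core clock genes differed in both directions. Clk, which encodes the activator of the clock loop, had a level of 9.73 ± 0.10 at ZT3 (SD, n = 3) and 7.22 ± 0.16 at ZT15 (SD, n = 2), a difference of -2.50 (SE 0.16) or 5.68-fold. The values of per, tim and vri were higher at ZT15. per, which encodes a repressor of the clock loop, differed by 1.98 (SE 0.14; 3.93-fold higher at ZT15), tim, which encodes the partner of the per protein, by 2.08 (SE 0.16; 4.24-fold), and vri, which encodes a repressor of Clk, by 2.10 (SE 0.22; 4.28-fold). A second tim probe set differed by 2.36. cry, which encodes the blue-light receptor of the clock, differed by -1.79 (SE 0.16; 3.45-fold lower at ZT15). Adjusted over the list alone, per, tim and vri were higher and Clk and cry lower. The other core clock genes did not pass: cwo differed by 0.98 (SE 0.61), Pdp1 by 0.63 (SE 0.36) and cyc, the partner of Clk, by -0.01 (SE 0.19). The cwo difference was 0.483 without ZT3 replicate 1 and 1.425 without ZT15 replicate 2. With the 2-array block, cwo (1.19) and Pdp1 (0.74) also passed over the list alone. A second cwo probe set differed by 0.34 (SE 0.17), and by 0.38 with the block.

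Over all probe sets the adjusted p in limma was 0.26 for Clk, per and tim, 0.407 for cry and 0.684 for vri. With the block it was 0.113 for Clk, per, tim and vri and 0.136 for cry. The differences of the clock genes were alike within the 2-array set and within the other arrays: -2.51 and -2.45 for Clk, 1.93 and 2.00 for per, 2.21 and 2.02 for tim, 2.14 and 1.96 for vri, and -1.61 and -1.91 for cry. Across the 8 core clock genes these pairs of differences correlated at r = 0.991, with the same sign in 7. Across the 9659 genes tested they correlated at r = -0.0599, with the same sign in 53.1%. Genes are not independent replicates in either correlation.

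No probe set passed an adjusted p of 0.05 in limma: 0 of 12105 were called, 284 had an unadjusted p under 0.05, where 605 are expected by chance, and the smallest adjusted p was 0.26. With the block, 0 were called and 1451 had an unadjusted p under 0.05. With both arrays of the 2-array set left out, 2323 probe sets were called, from 1 ZT15 array against 2 ZT3 arrays that also differed in gut list level, 10.47 against 5.47 and 4.96. Of the 10 genes of smallest p, 5 lay outside the core clock list, and none passed the threshold. CG34134 differed by -2.20 (SE 0.16, adjusted p = 0.26). Hr38, which encodes a nuclear receptor, differed by -2.46 (SE 0.24, adjusted p = 0.60), Jhe, the juvenile hormone esterase gene, by -2.20 (SE 0.27, adjusted p = 1.00), Cpr72Ec, a cuticle protein gene, by -2.16 (SE 0.29, adjusted p = 1.00) and CG15745 by -1.31 (SE 0.17, adjusted p = 1.00). All 5 had lower values at ZT15 within the 2-array set and within the other arrays, from -1.57 to -2.31 and from -1.13 to -2.83. They were chosen by p over these same arrays, so this likeness in sign was largely fixed by the choice.

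As groups, 8 of the 22 lists differed from other genes between ZT15 and ZT3 by camera. The core clock list was shifted up, with a median of 0.81 over 8 genes (adjusted p = 0.0061). The phototransduction list was shifted down, with a median of -0.27 over 19 genes (adjusted p = 5.95e-04), as were the synapse list, neuronal channels and release machinery, with -0.23 over 26 (adjusted p = 0.0087), and the clock neuropeptides, with -0.15 over 13 (adjusted p = 0.0285). The gut list was shifted up, with a median of 1.42 over 17 genes (adjusted p = 5.95e-04), as were the proteasome list, with 0.18 over 38 (adjusted p = 8.85e-08), the odorant-binding proteins, with 0.25 over 31 (adjusted p = 0.0285), and the mitochondrial ribosomal proteins, with 0.08 over 69 (adjusted p = 0.0036). With an estimated correlation none held, at adjusted p = 0.864 for core clock, phototransduction, synapse, neuropeptides, gut and proteasome and adjusted p = 0.889 for the other lists named. Adjusted over the list alone, no member of the 7 lists other than core clock passed; with the 2-array block 1 did, Obp99a (1.51, SE 0.16).

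The list shifts differed between the sets of arrays. In the gut list the median difference was -0.18 within the 2-array set and 4.49 within the other arrays, and without ZT15 replicate 1 it was -0.99 (adjusted p = 0.0023). The gut genes of smallest p for a rhythm with the block were zetaTry, with 0.93 and 2.16, and Jon25Bii, with 0.74 and 6.25. Phototransduction genes had medians of -0.08 and -0.38, synapse genes 0.03 and -0.34, neuropeptides -0.10 and -0.34, and odorant-binding proteins 0.04 and -0.05, where the median over all tested probe sets was 0.01 within the 2-array set and -0.15 within the other arrays. In phototransduction, inaD (-0.69, SE 0.19) and inaC (-0.61, SE 0.17), genes of the signalling complex of photoreceptors, had the smallest p for a rhythm. Of the proteasome list, 12 members were paralogs known for expression in the testis, among them Prosbeta2R2 and Prosbeta5R1, a division made after the values were seen. Their median was 0.03 within the 2-array set and 1.29 within the other arrays, and that of the 26 other members was -0.00 and 0.24. With the 2-array block the calls of synapse (adjusted p = 0.10), mitochondrial ribosomal proteins (adjusted p = 0.294) and odorant-binding proteins (adjusted p = 0.369) were lost and that of the testis and accessory gland list appeared (adjusted p = 8.90e-09, but adjusted p = 0.909 with an estimated correlation).

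Every one of these 8 calls was lost or turned on leaving out at least 1 of the ZT3 or ZT15 arrays. Without ZT3 replicate 1, camera gave an adjusted p of 0.0532 for core clock and for gut and 0.116 for the neuropeptides. Without ZT3 replicate 2 it gave 0.119 for synapse, 0.115 for mitochondrial ribosomal proteins and 0.203 for odorant-binding proteins, and without ZT3 replicate 3 it gave 0.0565 for neuropeptides, 0.149 for synapse and 0.168 for both mitochondrial ribosomal and odorant-binding proteins. Without ZT15 replicate 1, the adjusted p was 0.257 for core clock, 0.893 for neuropeptides, 0.0599 for phototransduction, 0.0665 for synapse and 0.932 for proteasome, and the gut list was shifted down. Without ZT15 replicate 2, it was 0.088 for core clock, 0.0744 for phototransduction, 0.378 for synapse, 0.197 for mitochondrial ribosomal proteins and 0.75 for odorant-binding proteins. The median of the odorant-binding proteins was -0.24 without ZT15 replicate 2, -0.0037 without ZT3 replicate 3 and 0.58 without ZT15 replicate 1, and -0.01 with the 2-array block.

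The other 14 lists did not pass for ZT15 against ZT3, with adjusted p from 0.155 for lipid and carbohydrate metabolism to 0.678 for heat shock. Median differences were -0.11 for clock modifiers (kinases, phosphatases and ligases acting on clock proteins), 0.15 for genes known to cycle in heads, -0.17 for glia, -0.02 for fat body, -0.00 for muscle, -0.16 for hemocyte and 0.05 for testis and accessory gland genes. They were 0.01 for antimicrobial peptides, -0.05 for heat shock, -0.02 for cytochrome P450s, -0.02 for glutathione S-transferases, 0.08 for UDP-glycosyltransferases, -0.06 for cytosolic ribosomal proteins and -0.09 for lipid and carbohydrate metabolism. Median and mean or test differed in sign for the head cyclers, fat body, muscle, cytochrome P450s and UDP-glycosyltransferases. Over the list alone, 2 head cyclers were higher and 2 lower, and no member of the others passed. With the 2-array block, 3 head cyclers were higher and 3 lower, 2 UDP-glycosyltransferases were higher and 5 lower, among them Ugt305A1 (1.34, SE 0.22) and Ugt35B1 (-1.86, SE 0.20), the fat body genes Lsp2 (1.03, SE 0.15) and fit (0.75, SE 0.16) and the testis gene Mst98Ca (2.07, SE 0.23) were higher, and GstZ2 (-1.51, SE 0.14) was lower. Left-out arrays brought in calls of 3 of these lists by camera. The testis and accessory gland list was shifted up without ZT15 replicate 2 (median 3.93) and without ZT3 replicate 2 (0.94) or 3 (0.99), and down without ZT15 replicate 1 (-3.48). The antimicrobial list was shifted up without ZT15 replicate 2 (0.67) and down without ZT15 replicate 1 (-0.97), and the cytochrome P450s were shifted up without ZT3 replicate 1 (0.18) or ZT15 replicate 1 (0.39).

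Over the whole day, 4 transcripts followed a 24 h curve, and 3 of them were core clock genes. Clk had an amplitude of 1.28 (SE 0.06), peaked at ZT2.0 (SE 0.25 h) and reached 5.90-fold from trough to peak (limma's adjusted p = 0.0024). per peaked at ZT13.7 (SE 0.38 h) with an amplitude of 1.02 (SE 0.08, limma's adjusted p = 0.023), and cry at ZT5.3 (SE 0.38 h) with 1.10 (SE 0.10, adjusted p = 0.041). The fourth was CG34134, with the largest amplitude, 2.49 (SE 0.13, 31.4-fold from trough to peak), at ZT22.8 (SE 0.17 h, adjusted p = 0.0024). tim had an amplitude of 1.09 (SE 0.12) at ZT15.4 and vri 1.15 (SE 0.13) at ZT13.6, each with an adjusted p of 0.13. The second tim probe set had 1.21 (SE 0.32) at ZT12.7 and did not pass (adjusted p = 0.966, and 0.231 with the 2-array block). Adjusted over the list alone, Clk, per, cry, tim and vri all passed. cwo (0.55, SE 0.24, at ZT16.3), Pdp1 (0.36, SE 0.16, at ZT14.4) and cyc (0.10, SE 0.12) did not; with the 2-array block cwo (0.59, SE 0.12) and Pdp1 (0.39, SE 0.08) passed over the list alone. A second cwo probe set had 0.18 (SE 0.07) with the block and an unadjusted p of 0.112, and with the probe sets of a gene averaged the amplitude of cwo was 0.36 without and 0.38 with the block. The labels do not say whether the strain is wild type or a clock mutant, nor whether cwo itself is intact in it, so the levels and amplitudes of cwo and the other clock genes stand for this strain alone.

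**Figure D2:**
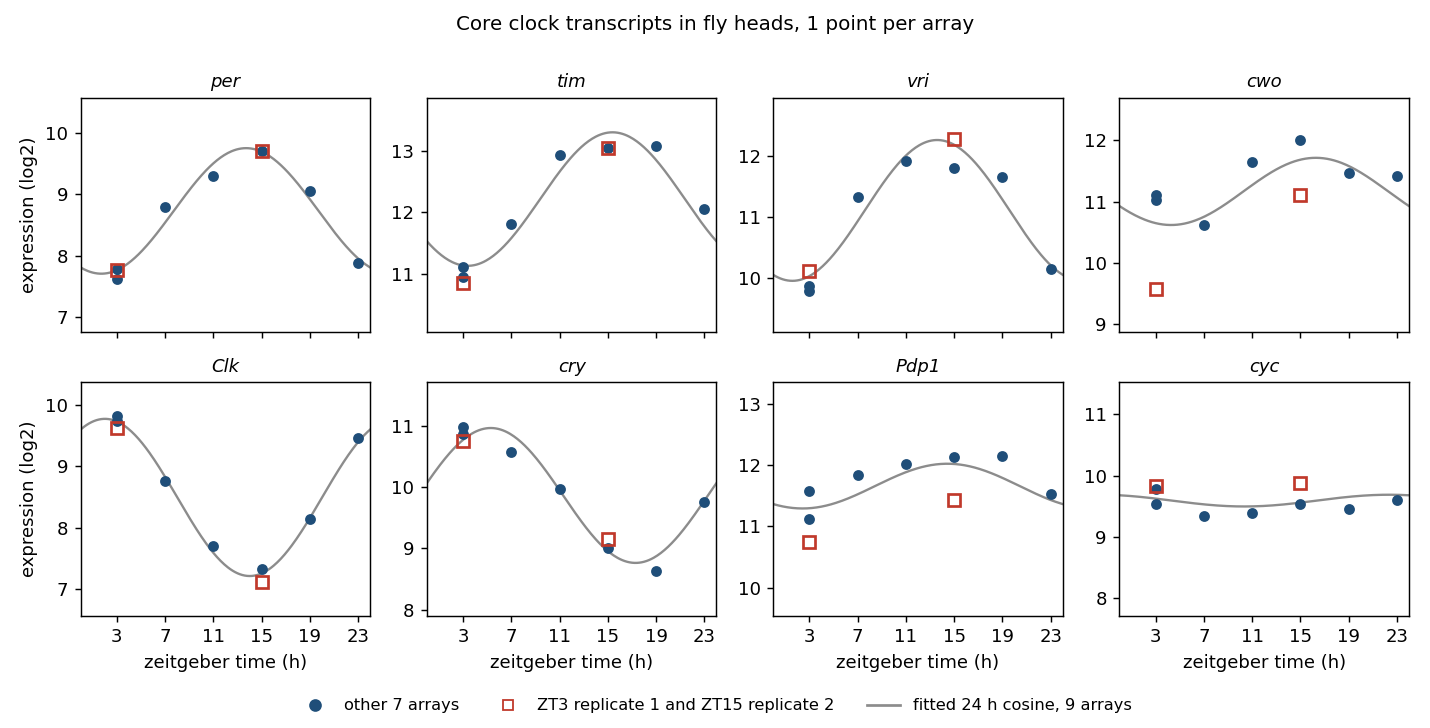
Levels (log2) of the 8 core clock genes against zeitgeber time (h), with 1 point per array: filled circles are the other 7 arrays, open squares the 2-array set, and the line a 24 h cosine fitted to all 9 arrays. per, tim and vri peak at ZT13.7, ZT15.4 and ZT13.6, Clk at ZT2.0 and cry at ZT5.3; in cwo and Pdp1 the open squares lie below the other points of the same time.

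The 6 other genes of smallest p for the rhythm did not pass over all probe sets. They were tim, vri, Cpr100A (1.07, SE 0.11, adjusted p = 0.10), CG15745 (0.66, SE 0.08, adjusted p = 0.21), Cpr72Ec (1.08, SE 0.13, adjusted p = 0.21) and CG7214 (2.41, SE 0.30, adjusted p = 0.21). Of the 12105 probe sets, 524 had an unadjusted p under 0.05, where 605 are expected by chance. The count of 4 was 11 without ZT15 replicate 2, and 2 without ZT3 replicate 2, ZT3 replicate 3 or the ZT11, ZT15 replicate 1, ZT19 or ZT23 array. In these 6 cases and without ZT3 replicate 1, per (adjusted p from 0.054 to 0.278) and cry (adjusted p from 0.131 to 0.306) lost their calls, while Clk and CG34134 kept theirs. The count was 1177 with array weights, 1 with arrays centred on their medians, 56 with the testis and accessory gland covariate, 72 without the 2-array set, and 0 with 1 mean per time, with time as a factor or with a 12 h cosine.

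With the 2-array set as a block, 30 probe sets of 28 genes followed a 24 h curve, and all 4 above were among them. tim (adjusted p = 0.025) and vri (adjusted p = 0.047) joined Clk, per and cry. Both lost this call on leaving out any 1 of the 9 arrays, with adjusted p from 0.0511 to 0.147 for tim and from 0.0568 to 0.20 for vri. Both also lost it with quantile normalization (adjusted p = 0.0503 and 0.0627) and with the testis and accessory gland covariate (0.0995 and 0.131), tim with its probe sets averaged (0.0906) and vri with no filter (0.0623). By peak time, 12 genes peaked from ZT0 to ZT4, 7 from ZT4 to ZT8, 2 from ZT8 to ZT12, 4 from ZT12 to ZT16, 1 from ZT16 to ZT20 and 2 from ZT20 to ZT24. In the 7 arrays outside the 2-array set, gut list medians were 5.47 and 4.96 at ZT3 and 8.77 to 10.47 at other times. The excess of peaks near ZT3 was not told apart from this difference between arrays. Among the genes peaking from ZT0 to ZT4 were several of known function. Ugt35B1, a UDP-glycosyltransferase, peaked at ZT3.3 (amplitude 0.96, SE 0.08), GstZ2, a glutathione S-transferase, at ZT3.1 (0.78, SE 0.06), and Jhe at ZT4.0 (1.20, SE 0.09). The cuticle protein gene Cpr72Ec peaked at ZT3.5 (1.10, SE 0.07), the chitin-binding protein gene Gasp at ZT7.1 (0.71, SE 0.08) and the cuticle protein gene Cpr100A at ZT8.7 (1.07, SE 0.07). The lowest levels of Gasp and Cpr100A, 8.72 and 7.23, were those of the single ZT19 array. CG7214 had an amplitude of 2.41 (SE 0.14) at ZT8.9. The remaining genes named by amplitude were CG42329 (1.35), CG13305 (1.28), CG5402 (0.99), lncRNA:CR32553 (0.87), Sidpn (0.78), CG31321 (0.70) and CG15745 (0.67), of which CG5402 peaked at ZT14.6, lncRNA:CR32553 at ZT22.9 and the others between ZT1.1 and ZT5.7. CG5402 was low in the 2-array set, as were the testis and accessory gland genes: it had levels of 2.52 and 3.99 there and from 7.63 to 9.79 in the other 7 arrays, and an unadjusted p of 0.772 in limma without the block. Adjusted p for these 20 genes ran from 7.14e-04 for Clk to 0.048 for CG5402 and CG15745.

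The count with the block moved with single arrays: it was 68 without ZT3 replicate 1 or ZT15 replicate 2, 10 without ZT7, 7 without ZT11, 5 without ZT23, 4 without ZT3 replicate 2, ZT3 replicate 3 or ZT15 replicate 1, and 2 without ZT19. With the testis and accessory gland covariate beside the block 12 were called, 8 of them among the 30; of the 20 named genes, Clk, CG34134, CG7214, CG42329, Cpr100A, Ugt35B1 and lncRNA:CR32553 passed there.

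**Figure D3:**
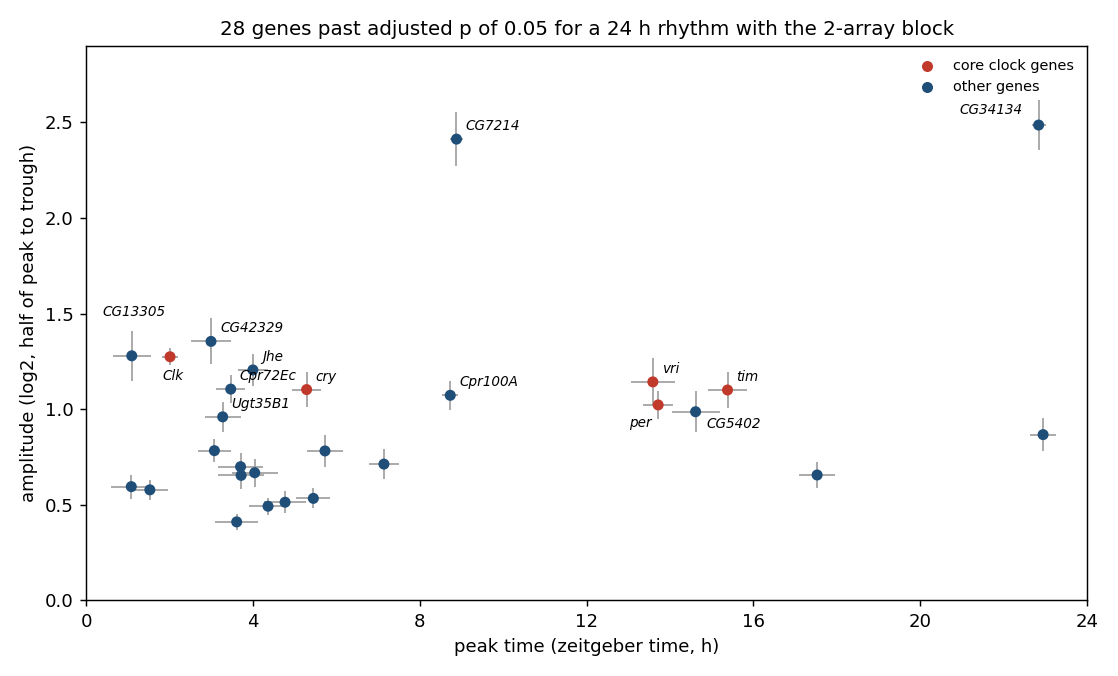
Amplitude (log2) against peak time (zeitgeber time, h) of the 28 genes past the threshold for a 24 h rhythm with the 2-array block; each point is 1 gene, bars are standard errors from limma, and red marks core clock genes. CG34134 (2.49) and CG7214 (2.41) have the largest amplitudes, and 19 of the genes peak between ZT0 and ZT8.

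Among the lists, the core clock genes were enriched among rhythmic genes, with 3 of 8 against 4 of all 9659 genes (Fisher exact test, adjusted p = 3.28e-08), and no other list was. Without ZT3 replicate 1, where Clk was the only core clock gene past the threshold, 0 lists passed. With the block 3 lists passed: core clock with 5 of 8 (exact adjusted p = 1.72e-10), genes known to cycle in heads with 2 of 18 (Ugt35B1 and CG9649, exact adjusted p = 0.0099) and UDP-glycosyltransferases with 2 of 19 (Ugt35B1 and Ugt36F1, exact adjusted p = 0.0099), 28 of the 9659 genes being rhythmic. The head cycler and UDP-glycosyltransferase calls share Ugt35B1. This gene lost its call with the block on leaving out any array outside the 2-array set.

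Adjusted over the list alone, 4 of the 18 head cyclers followed a 24 h curve, namely Achl, Usp8, Slob and CG9649, and 10 did with the block. With the block, Achl had an amplitude of 2.74 (SE 0.33) at ZT21.9 and Usp8, a ubiquitin protease gene, 0.90 (SE 0.12) at ZT11.1; Slob, which encodes a protein binding a potassium channel, had 0.45 (SE 0.06) at ZT12.7, and CG9649 0.41 (SE 0.04) at ZT3.6. Without the block, Hsc70-3, an endoplasmic reticulum chaperone gene, was the only member of any other list to pass over its list alone (0.35, SE 0.08, at ZT8.9).

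With the block, members of the UDP-glycosyltransferase, glutathione S-transferase and cytochrome P450 lists, families of detoxification enzymes, passed when adjusted over the list alone. In that fit 2045 of the 12105 probe sets had an unadjusted p under 0.05 in limma, where 605 are expected by chance. Passing over a short list alone therefore does not show a rhythm of that list, here or below. Of 19 UDP-glycosyltransferases 10 passed, 5 of them peaking from ZT0 to ZT6, with amplitudes from 0.24 to 0.96; among them were Ugt35B1 (0.96) and Ugt36F1 (0.59, SE 0.06). Of 31 glutathione S-transferases 9 passed, 7 of them peaking from ZT0 to ZT6, among them GstZ2, with amplitudes from 0.20 to 0.78. Of 71 cytochrome P450s 5 passed, namely Cyp6d2 (0.89, SE 0.11, ZT20.4), Cyp6a21 (0.59, SE 0.10, ZT1.4), Cyp305a1 (0.51, SE 0.07, ZT5.6), Cyp4p1 (0.39, SE 0.05, ZT3.2) and Cyp4ac1 (0.36, SE 0.06, ZT20.3). Of the tested members, 44 of 71 cytochrome P450s (62.0%), 15 of 31 glutathione S-transferases (48.4%) and 12 of 19 UDP-glycosyltransferases (63.2%) were higher in both arrays of the 2-array set than in all 7 others, as were 38.6% of all tested probe sets.

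Among the other lists, 3 of 12 antimicrobial genes passed with the block over their list alone, with peaks from ZT8.3 to ZT9.7: edin (1.69, SE 0.37, ZT9.7), DptB (0.85, SE 0.17, ZT8.5) and PGRP-SB1 (0.48, SE 0.10, ZT8.3). None of the 12 passed without the block, and 5 of them were lower in both arrays of the 2-array set than in all 7 others, where 17.3% of all tested probe sets were; the median difference of the 7 from the 2 arrays was 1.03. Of 31 odorant-binding proteins, 4 passed with the block: Obp56f (0.79, SE 0.16), Obp83cd (0.75, SE 0.11), Obp99a (0.74, SE 0.13) and Obp8a (0.39, SE 0.08). Of 19 phototransduction genes, 2 did: inaD (0.35, SE 0.07, ZT2.1) and inaC (0.34, SE 0.06, ZT4.4). mdy, which encodes an enzyme of triglyceride synthesis, passed among 28 metabolic genes (0.42, SE 0.05, ZT23.1), and Hsc70-3 again among 7 heat shock genes. Of 19 testis and accessory gland genes 6 passed, all peaking from ZT12 to ZT18, among them Mst98Ca (0.97, SE 0.18, ZT14.2) and SP (0.74, SE 0.15, ZT15.2), the sex peptide gene. This list and the gut list were both lowest at ZT3 among the 7 arrays outside the 2-array set. Medians of the testis and accessory gland list and of the gut list were 9.79 and 5.47 in ZT3 replicate 2, 9.75 and 4.96 in ZT3 replicate 3, 10.80 and 8.77 at ZT7, 11.72 and 9.90 at ZT11, 11.68 and 10.47 in ZT15 replicate 1, 11.52 and 10.12 at ZT19, and 10.78 and 9.78 at ZT23.

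With or without the block, no member passed over the list alone for clock modifiers (smallest p with the block: Atx2, amplitude 0.24, and dco, 0.22), clock neuropeptides (NPFR, 0.35, and ITP, 0.40), synapse (Vmat, 0.62, and VGlut, 0.55), glia (Indy, 0.17, and Gli, 0.18), fat body (Npc2b, 0.27, and fit, 0.29), muscle (Prm, 0.29, and Mlc2, 0.45), hemocyte (eater, 0.21, and srp, 0.18) and gut (zetaTry, 0.85, and Jon25Bii, 2.21). The same held for cytosolic ribosomal proteins (RpS28a, 0.19, and RpS5b, 0.25), mitochondrial ribosomal proteins (mRpS11, 0.23, and mRpL41, 0.24) and proteasome (Prosbeta2R2, 0.55, and Prosbeta3, 0.20). In the ovary and dosage compensation lists, with 3 and 1 tested members, Vm26Aa (0.23), CycB3 (0.16) and msl-2 (0.09) did not pass.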

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

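The fits with the 2-array set as a block, without it, with the testis and accessory gland covariate, and all alternatives of the rhythm with the block were chosen after the data had been seen. The count of 0 for ZT15 against ZT3 was the same in 24 settings, and was 2323 without the 2-array set, where 1 ZT15 array remained. Directions of the named genes were the same in every setting run for ZT15 against ZT3 except for cyc, which was 0.0145 with quantile normalization and 9.81e-04 with array weights, and ran from -0.19 to 0.17 on leaving out each array. Log2 of the deposited values gave the same counts for ZT15 against ZT3 and for the rhythm without the block, and was not run for the others. This setting multiplies all values by a constant and mainly changes which probe sets pass the filter. The counts could thus hardly differ and do not test the choice of scale.

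The 4 rhythmic probe sets became 1 with arrays centred on their medians, 1177 with array weights, 0 with 1 mean per time, 0 with time as a factor, 0 with a 12 h cosine, 30 with the 2-array block, 72 without the 2-array set, 56 with the covariate and 12 with block and covariate. Leaving out each array gave 2 to 11. Time as a factor and 1 mean per time leave fewer residual degrees of freedom; for the other changes the cause was not tested. Time as a factor and the 12 h cosine left 0 calls, so all 4 lost theirs there. In the other 25 settings, Clk lost its call in 2, CG34134 in 1, and per and cry in 10 each, while tim and vri gained a call in 3.

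The 30 probe sets with the block became 13 with quantile normalization, 53 with a filter at 7, 99 with trend and robust, 117 at an adjusted p of 0.10 and 12 with the covariate, and 2 to 68 on leaving out each array; the cause was not tested. Clk and CG34134 kept their call in all 18 settings run with the block. Centring arrays on their medians, array weights and 1 mean per time were not among these. Without the block, Clk lost its call with centring, and both genes lost theirs with 1 mean per time. For the genes called, the largest shift of peak time between fits with and without the block was 0.285 h. The 2-array set was nearly unrelated to the 24 h curve of the real times (r squared 0.00539), so a small shift was set by the design.

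The 8 list shifts became 6 with the 2-array block and 0 with an estimated correlation, and 5 to 8 on leaving out each array. On leaving out each array, the median of the gut list ran from -0.99 to 4.02, that of the mitochondrial ribosomal proteins from -0.18 to 0.32 and that of the proteasome list from 0.066 to 0.26, where the test at the lowest value pointed down; that of the odorant-binding proteins ran from -0.24 to 0.58, where the test at the lowest value still pointed up. The median of the core clock list ran from 0.41 to 1.2, that of phototransduction from -0.36 to -0.12 and that of the neuropeptides from -0.45 to -0.0047. The cause was not tested. The 1 list enriched among rhythmic genes became 3 with the 2-array block, and 0 to 1 on leaving out each array.

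The replicate numbers did not pair the arrays. Deviations from the group mean correlated at r = -0.865 between the arrays numbered 1 and at -0.812 between those numbered 2 across probe sets, which are not independent. The deviations of the 2 ZT15 arrays are exact opposites by construction. Both values therefore restate the split that sets ZT3 replicate 1 with ZT15 replicate 2, and are not separate evidence. With the replicate block 0 probe sets were called for ZT15 against ZT3, and 5 lists were shifted, with the calls of neuropeptides, synapse, mitochondrial ribosomal and odorant-binding proteins lost and that of the testis and accessory gland list gained (median 0.99, adjusted p = 0.015). Low signal limits the list levels near 3 on the log2 scale, where background and expression are not separated.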

Other observations

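The tests on male transcripts and on the split of the arrays were chosen after that split had been seen, the cuticle list and its test without ZT19 were made after the table of rhythmic genes had been seen, and the times were reassigned within the sets for the fit without the block after the other counts had been seen.

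Of the 16 muscle list genes, 3 ranged over more than 3 on the log2 scale between arrays, and the other 13 over 0.47 to 2.26. On the single ZT11 array 10 of the 16 had their highest level. The list's median was 11.55 there and 10.07 to 10.97 on the other arrays. Act88F, the flight muscle actin gene, had a level of 12.8 at ZT11, between 6.4 and 6.7 in ZT3 replicates 2 and 3, ZT7 and ZT15 replicate 1, 8.4 and 8.3 at ZT19 and ZT23, and 8.6 and 9.4 in the 2-array set. fln, which encodes flightin, had 11.4 at ZT11 and 4.4 in ZT15 replicate 1. TpnC4, a troponin C gene, had 7.0, 8.6 and 9.0 at ZT11, ZT19 and ZT23 and between 2.9 and 3.5 elsewhere. Lsp2, a storage protein gene of the fat body, had 10.7 and 10.5 in ZT3 replicates 2 and 3 and 14.5 in ZT15 replicate 2. These genes were singled out after their values were seen, and times with 1 array have no replicate check.

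The 2-array set was not only lower in male transcripts. Of the 12105 tested probe sets, 2093 (17.3%) were lower in both of its arrays than in all 7 others and 4677 (38.6%) were higher. Chance gives 2.78% each for a pair of arrays named beforehand, but this pair was picked from these same data. The median over all probe sets of the other 7 minus the 2 arrays was -0.20. The mitochondrial ribosomal proteins had a median of -0.49 (SD 0.15 over members), with 65 of 69 higher in the 2 arrays, and 22 of 31 tested odorant-binding proteins were higher there.

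Transcripts of male reproductive organs were abundant in 7 of the 9 arrays of heads: Acp98AB, a seminal fluid protein gene, lay between 12.3 and 14.2 there and at 4.3 and 3.2 in the 2-array set, where 2 and 4 of the 19 list members reached 5. Time of day is not enough to account for this, since the list's mean in ZT3 replicates 2 and 3 exceeded that in ZT3 replicate 1 by 5.57. A shift from normalization of low values is argued against by the ovary list, whose median difference between the 7 and the 2 arrays was -0.11. The added bioB control also differed along this split, with 9.38 and 9.28 in the 2-array set and 7.43 to 9.04 in the others. The cause of that difference was not tested. RNA of male bodies in the head samples may be a source, and stays open: 6 of the 18 gut genes were lower in both of the 2 arrays than in all 7 others, while others, such as LManV with 6.0 and 5.3 in ZT3 replicates 2 and 3, were also low in ZT3 arrays that carried male transcripts. Sex and collection of the flies, which the labels do not give, were not tested.

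Whether the rhythm counts exceed chance was not settled. Of 100 assignments of the same times to the 9 arrays, the real one included, 3 reached the real count of 4. These assignments ignore the split of the arrays. With times reassigned only within the 2-array set and within the other 7, 1 of 100, the real one, reached 4 without the block. The highest other count was 1. This does not exclude chance, because arrays within the 7 are not freely exchangeable. ZT3 replicates 2 and 3 correlated at r = 0.994, and at 0.915 to 0.964 with the rest of the 7. Reassignments that part this pair thus differ from the real times in more than time. The highest count over all 9 arrays was 2908. Both of the other assignments that reached 4 calls, with 849 and 2908, had times whose 24 h curve followed the split of the arrays. Their r squared was 0.485, against 0.00539 for the real times and a median of 0.218 over the others. However, 16 assignments with at least that r squared had no call, so following the split is not enough to give such counts. What else these assignments followed was not tested. Of 100 assignments within the 2 sets of arrays, 5 gave at least the real 30, and the highest other was 1542, so chance is not excluded for the count with the block. Of the 100 probe sets of smallest p on the 7 arrays alone, 63 had the same sign of ZT15 minus ZT3 in the 2 other arrays, against 52.5% of all tested, with r = 0.537 across the 100; body RNA without any signal of time cannot be told apart from a weak signal of time in these probe sets, because the value lies between those that would separate them. In the core clock list, fixed beforehand, the differences within the 2 sets of arrays correlated at r = 0.991. Their sign was the same in 7 of the 8 genes. Over all genes tested r was -0.0599. For the core clock genes these values argue against body RNA without any signal of time.

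Cuticle genes may follow a 24 h curve as a group, or differ between single arrays. Of 50 cuticle and chitin-binding genes tested, 4 were called rhythmic with the block (Cpr72Ec, Cpr100A, TwdlT and Gasp). Among the 46 others, 14 (30.4%) had an unadjusted p under 0.05, against 16.6% of 9585 other genes (one-sided Fisher exact p = 0.0150), and 12 of these 14 peaked from ZT4 to ZT12. Of the 18 with a p under 0.05, 14 were lowest on the single ZT19 array, as were 23.5% of all genes, but without that array 13 of the same 46 (28.3%), 12 of them among the 14, had a p under 0.05, against 12.1% of 9543 others (one-sided Fisher exact p = 0.00259), which argues against ZT19 as the whole source. These tests treat genes as independent, so an amount of cuticle that differed between arrays stays open; without ZT19 only 2 probe sets were called with the block, and the count from which the group was drawn was met by 5 of 100 assignments.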
